A study of Homo sapiens with 2 samples.

How the data were processed

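ChIPmentation, a chromatin immunoprecipitation in which the sequencing adapters are inserted by Tn5 transposase on the immobilised chromatin, was carried out in PANC-1, an established human pancreatic ductal adenocarcinoma cell line. The series holds 2 samples, 1 treated with the solvent DMSO and 1 with inflachromene, a small molecule known to bind the high-mobility-group proteins HMGB1 and HMGB2. Per the labels' protocols, cells were crosslinked in 15 mM EGS for 30 min and then in 1% formaldehyde for 10 min, and the reaction was stopped with 125 mM glycine. The antibody's target, the dose and the duration of treatment are not given in the sources used here.

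Each sample was represented by 1 deposited peak list in narrowPeak layout. Per the submitters' processing notes, MACS2 and deepTools 3.5.6 were used with the hg38 build; the MACS2 version, the aligner, the handling of duplicate fragments and any pooling before peak calling are not given in the sources used here. Each deposited row holds the peak's position, an integer score, the fold enrichment at the summit (a ratio of pileup to local background), the −log10 p-value and −log10 q-value at the summit, and the summit's offset. The score column was not used further. The lowest deposited −log10 q was 3.02 in DMSO and 3.01 in inflachromene, so the authors' cutoff appears to have been q = 0.001. No peak overlapped another of its own list, so no merging was needed.

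The lists give no read counts, and the number of fragments over each summit, its pileup, was recovered from the deposited values. MACS2 writes the fold enrichment as (pileup + 1)/(background + 1) and the p-value as the Poisson probability of a pileup above the observed one, so both values together fix a whole-number pileup and its background. A whole pileup that matched the deposited −log10 p within 0.001 was found for every peak of both lists on the assembled chromosomes. On simulated data the same step returned the true pileup for all 2000 summits. Those data were made with the same formulas and with backgrounds below the highest found here. They therefore test neither the formulas nor such high backgrounds. The recovered background changed in even steps, of the size that 1 fragment end within a 10 kb window would give, with implied mean fragment lengths of 152.4 bp for DMSO and 165.7 bp for inflachromene. The narrowest peaks were 152 and 165 bp wide, as the caller's minimum width would be for paired-end fragments of those lengths. The background was therefore read as coming from the same library, with no separate control. These are inferences from the values, not statements by the authors, and no input or control library was used here. A position or gene is called bound where a peak was called, and whether a protein was bound there was not tested.

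The lowest background, which the caller sets from the total number of fragments, was 0.651 fragments per base in DMSO and 0.683 in inflachromene. Divided by the fragment lengths, this put the number of fragments in the inflachromene library at 0.964 times that in DMSO, mitochondrial and unplaced sequences included. The total itself depends on the genome size the authors set and is therefore not given.

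Peaks on chromosomes 1 to 22 and X were analysed, 15186 of 15354 in DMSO and 10836 of 10991 in inflachromene. A peak was called shared when it overlapped a peak of the other list by at least 1 bp. The overlap was set beside 100 random placements of the other list's peaks, which kept chromosome and width. Peaks were located by their summit against 20037 protein-coding genes of a RefSeq gene table of the GRCh38.p14 assembly, which has the same coordinates as hg38 on these chromosomes. That table gives no strand. A window of 1000 bp either side of both annotated ends of a gene therefore took the place of the planned promoter window, and a start cannot be told from a 3′ end. Genes were classed by whether a peak, or the peak of the other list that overlapped it, lay at an end, a rule set after a first count by each list's own summits had been seen. A genome sequence was not used here, so the planned comparison of 23 sequence motifs was not made.

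With 1 sample per treatment there was no replicate, no test between treatments was made and no p-value is given. Shares carry exact Clopper-Pearson 95% intervals and pileups exact Poisson 95% intervals; both cover counting error only, not the spread between cultures or libraries. The 22 gene lists with 529 genes, some of them in more than 1 list, were fixed before the data were examined, and all symbols matched the table. For each list the share of members with a DMSO peak was given as a percentile among 10000 random lists of the same size. The share of those members without an inflachromene peak, called the lost share, was given as a percentile among 10000 random lists matched on DMSO fold enrichment in 5 groups of equal size, where at least 5 members were bound. In simulated lists of 20 genes, 7 of 10 with a raised loss (50% against 20%) reached the 95th percentile, and 1 of 10 without. There all members were bound and loss did not depend on peak strength, unlike in the data. These rates therefore do not carry over to the lists here. Neighbouring genes can share a peak, so genes are not independent. The strongest DMSO peak of 2894 genes also lay at an end of another gene.

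Genes were named by a rule fixed beforehand: HMGB1 and HMGB2, the 6 genes of highest DMSO fold enrichment in both lists, the 8 of highest fold enrichment in each list alone, and up to 2 members per class from each gene list by fold enrichment. A class of 5 or fewer members could be named in full. Because of the gene table, this rule was applied to peaks at gene ends. Some genes that the rule names are not reported here. Alternatives covered the q and fold thresholds, the overlap rule, the list length and the gene-end window. The recovered pileup and every comparison made with it were added after the data were examined. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.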

Results

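The data consisted of 1 peak list from DMSO-treated PANC-1 cells and 1 from inflachromene-treated cells. On the assembled chromosomes 15186 peaks were called in DMSO and 10836 in inflachromene, 28.6% fewer. The DMSO peaks covered 5.25 Mb and the inflachromene peaks 3.73 Mb, with median widths of 305 bp and 308.5 bp. The median pileup at the summit was 23 fragments in both lists. The number of sequenced fragments was inferred to be 0.964 times as large in the inflachromene library as in DMSO. Each treatment had 1 sample, so the differences below have no replicate check and compare these libraries, not the conditions.

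The first comparison asked which positions called in control cells were also called after treatment with inflachromene. Of the DMSO peaks, 9796 (64.5%, 95% interval 63.7 to 65.3) overlapped an inflachromene peak and 5390 did not. Of the inflachromene peaks, 9794 (90.4%, 89.8 to 90.9) overlapped a DMSO peak and 1042 did not. DMSO peaks alone were thus 5.17 times as many as inflachromene peaks alone. Random placements gave overlaps of 0.332% and 0.474% on average. When both lists were held to the length of the shorter, 79.4% of the DMSO peaks and 79.6% of the inflachromene peaks overlapped.

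The positions without an inflachromene peak were mostly weak ones of the DMSO list, which the plot of overlap by strength shows. Each list was divided into 5 groups of equal size by the authors' fold enrichment. In the weakest group of the DMSO list, 32.4% (30.7 to 34.1) of the peaks had an inflachromene peak. The share was 44.5%, 62.6% and 84.7% in the following groups and 98.4% (97.9 to 98.8) in the strongest, where 48 of 3037 peaks had none. In the inflachromene list the corresponding shares ran from 75.3% (73.4 to 77.1) in the weakest group to 99.8% (99.53 to 99.95) in the strongest. The middle groups had the same median pileup of 21 fragments, and 62.6% of these DMSO peaks against 93.3% of these inflachromene peaks were overlapped. DMSO peaks alone had a median width of 213 bp and a median fold enrichment of 6.36, against 373 bp and 9.31 for shared DMSO peaks.

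**Figure D1:**
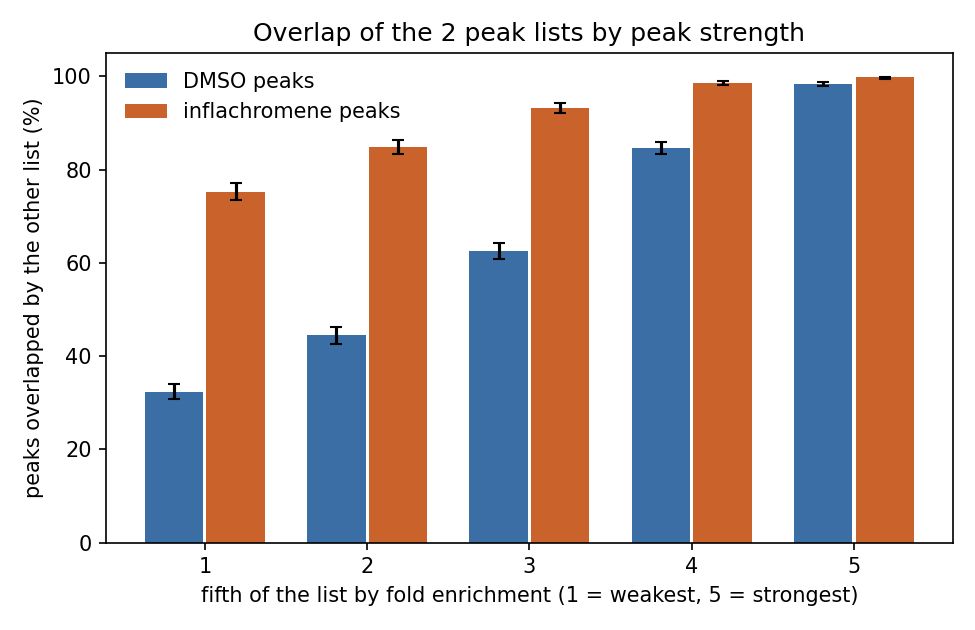
Share of peaks overlapped by at least 1 bp by a peak of the other list (%, vertical axis), for 5 equal groups of each list by the authors' fold enrichment (horizontal axis); bars are DMSO and inflachromene peaks, and error bars are exact 95% binomial intervals. The DMSO bars run from 32.4% to 98.4% and the inflachromene bars from 75.3% to 99.8%.

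At most positions with a peak in both lists, the summit held fewer fragments in the inflachromene library. Over 9796 shared peaks the median ratio of inflachromene to DMSO pileup was 0.833, and the pileup was lower in inflachromene at 74.7% of them. At the 1297 shared peaks with a mean pileup of 50 or more, the median ratio was 0.804 (bootstrap 95% interval 0.794 to 0.817) and 87.5% were lower. Both medians lay below the ratio of fragment numbers, 0.964, as the plot of summit pileup shows. Shared peaks exclude positions that dropped below the calling threshold in either library.

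**Figure D2:**
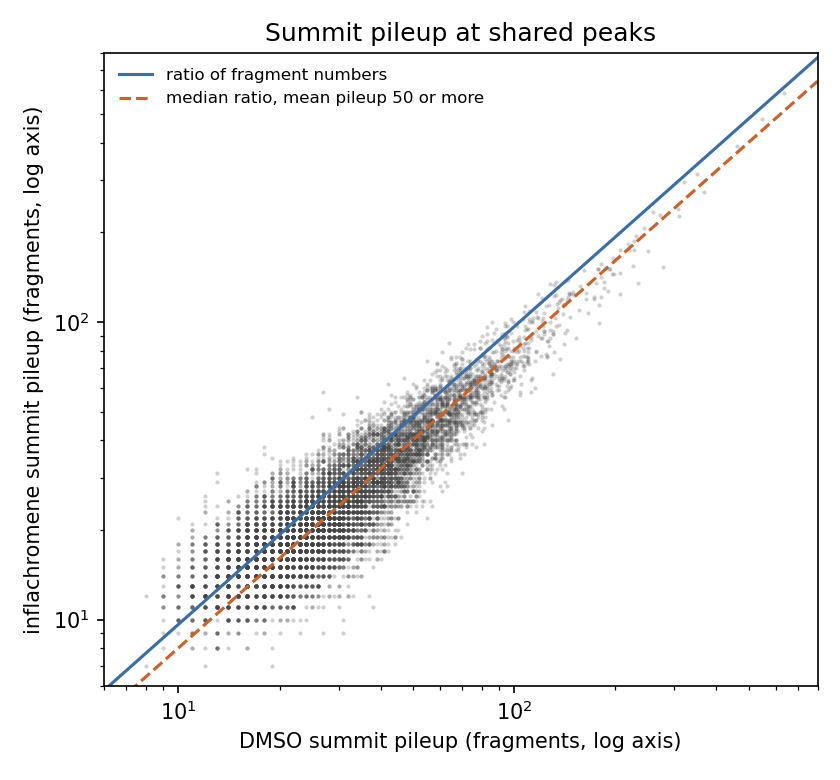
Summit pileup in fragments at each shared peak, DMSO on the horizontal and inflachromene on the vertical axis, both logarithmic; the solid line is the ratio of fragment numbers (0.964) and the dashed line the median ratio at peaks with a mean pileup of 50 or more (0.804). Most strong peaks lie below the solid line.

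The second comparison concerned where in the genome the peaks lay. At ends of protein-coding genes lay 54.1% (53.3 to 54.9) of the DMSO peaks and 61.0% (60.1 to 61.9) of the inflachromene peaks, against 3.03% and 3.10% of randomly placed peaks. Shared DMSO peaks were at gene ends in 64.0% (63.0 to 64.9) of cases, DMSO peaks alone in 36.3% (35.0 to 37.6) and inflachromene peaks alone in 34.9% (32.0 to 37.9). Seen from the control, 23.8% (22.9 to 24.7) of the DMSO peaks at gene ends had no inflachromene peak. The share was 48.3% (46.66 to 49.95) inside genes and 50.4% (48.7 to 52.1) between genes. The DMSO peaks inside and between genes were also weaker, with median pileups of 20 fragments each against 27 at gene ends.

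At the level of genes, 7304 of 20037 protein-coding genes had a peak at an end in both lists, 1850 in DMSO alone and 317 in inflachromene alone. Thus 20.2% (19.39 to 21.05) of the 9154 genes bound in DMSO had no inflachromene peak. The genes of the 2 proteins that inflachromene binds were among those with a peak in both lists. At HMGB2, on chromosome 4 (DMSO peak 173334355 to 173334769), the summit held 71 fragments in DMSO (Poisson interval 55.5 to 89.6) and 43 in inflachromene (31.1 to 57.9), with fold enrichments of 17.7 and 11.6. At HMGB1, on chromosome 13 (30617445 to 30618022), it held 46 (33.7 to 61.4) and 42 (30.3 to 56.8) fragments, with fold enrichments of 14.7 and 13.8; this peak also lay at an end of USPL1. The intervals of the 2 libraries overlapped at both genes, which does not by itself compare the 2 counts. The ratio of inflachromene to DMSO pileup was 0.606 at HMGB2 and 0.913 at HMGB1, against a median of 0.822 over all genes with a peak in both lists.

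Among genes with a peak in both lists, 6 were named by the highest DMSO fold enrichment. Their peaks lay at RABGGTB (chromosome 1, 75786015 to 75786389), encoding a subunit of Rab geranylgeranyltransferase, and at GOLGA5 (chromosome 14, 92793900 to 92794464), encoding a golgin. The others were at TSN (chromosome 2), RWDD1 and RPS12 (chromosome 6) and RABL2B (chromosome 22). Their DMSO fold enrichments ranged from 30.6 at RABGGTB down to 27.2 at RABL2B. Choosing genes by their DMSO value favours a lower inflachromene value, here and for the members named from each list below, unlike the choice of peaks by mean pileup above. The inflachromene pileup was lower at all 6, with 91 against 130 fragments at RABGGTB, 135 against 233 at GOLGA5 and 99 against 179 at TSN. It was 227 against 309 at RWDD1, 173 against 251 at RPS12 and 67 against 130 at RABL2B.

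Among genes with a peak in DMSO alone, the highest fold enrichment was at BTN2A2, a butyrophilin gene on chromosome 6 (26382955 to 26383221), where the summit held 44 fragments at 17.0-fold. RPL34, encoding a ribosomal protein of the large subunit, followed with 29 fragments at 14.4-fold on chromosome 4 (108620426 to 108620679). A single peak on chromosome 1 (74198039 to 74198370), with 29 fragments, lay at ends of LRRIQ3, FPGT and FPGT-TNNI3K. MARS2, the mitochondrial methionyl-tRNA synthetase gene, had 34 fragments at 13.6-fold. UFL1, the ligase gene of the UFM1 pathway, had 25 fragments at 13.3-fold, and PDCD7 had 28 at 12.9-fold. Among genes with a peak in inflachromene alone, the highest fold enrichment of that list was at POLR2C. This subunit gene of RNA polymerase II on chromosome 16 (57462549 to 57462749) had 17 fragments at 9.80-fold. Others were EDEM2 (24 fragments), ZNF134 (21), UBE2K (24), MIS18A (14), FGF22 (22) and VPS8 (21), at 8.44-fold or more.

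The third comparison addressed the pro-proliferative programmes named in the series title. Of the 30 genes in each of the lists for DNA replication and for mitosis, 83.3% and 90.0% had a peak in DMSO, against 45.7% of all protein-coding genes and 85.7% of 28 constitutively expressed genes. Of 30 replication and S phase genes, 22 had a peak in both lists, 3 in DMSO alone (RFC4, TYMS and CCNE2) and 1 in inflachromene alone (FEN1). MCM3, a subunit gene of the replicative helicase, had 77 fragments in DMSO and 59 in inflachromene, and TK1, encoding thymidine kinase, had 74 and 81. Of 30 mitosis and G2/M genes, 24 had a peak in both lists, 3 in DMSO alone (BUB1B, CENPE and BIRC5) and 2 in inflachromene alone (NDC80 and FOXM1). Several of these peaks also lay at an end of a neighbouring gene and cannot be credited to 1 gene. These neighbours included EIF4A2 for RFC4, AFMID for TK1, NDUFAF6 for CCNE2, TMEM258 for FEN1, METTL4 for NDC80 and RHNO1 for FOXM1. CDK1, the mitotic cyclin-dependent kinase gene, had 68 fragments in DMSO and 45 in inflachromene, and TPX2 had 80 and 65. The share of DMSO-bound members without an inflachromene peak was 3 of 25 (2.55 to 31.2%) for replication and 11.1% (2.35 to 29.2) for mitosis. These shares stood at percentiles 36.4 and 48.1 of random lists matched on strength.

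Of 25 MYC target and ribosome biogenesis genes, 20 had a peak in both lists and 3 in DMSO alone (POLR1B, WDR12 and UTP20), a lost share at percentile 51.1. The WDR12 peak also lay at an end of CARF. PA2G4, encoding a proliferation-associated protein, had 81 fragments in DMSO and 44 in inflachromene, and RRP9 had 75 and 47; both peaks also lay at an end of a neighbouring gene. All 26 genes of cytosolic ribosomal proteins had a peak in at least 1 list, with 22 in both, 3 in DMSO alone (RPL8, RPL23 and RPS3) and 1 in inflachromene alone (RPL13), at percentile 39.0. RPLP0 had 76 and 45 fragments and RPL27 46 and 32. Of 27 replication-dependent histone genes, 21 had a peak in both lists and 1, H3C10, in DMSO alone, at percentile 0.025. That percentile was 4.2 when random lists were matched on −log10 p in place of fold enrichment. Histone genes lie in clusters, and a window can hold ends of several.

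Of 15 HMG box and other high-mobility-group genes, 10 had a peak in both lists and 2 in DMSO alone, HMGA1 (31 fragments) and SMARCE1 (12), at percentile 19.9. The HMGA1 peak also lay at an end of LOC124901225. The list of MAPK feedback genes, 24 in all, had 13 in both lists, 3 in DMSO alone (EGFR, EPHA2 and SPRY4) and 1 in inflachromene alone (PLAU), at percentile 9.03. That percentile was 34.1 when matched on −log10 p and 0.43 with each peak assigned to the nearest gene end within 50 kb. ETV5, an ETS family transcription factor gene, had 91 fragments in DMSO and 71 in inflachromene. Of 24 AP-1 and immediate early genes, 20 had a peak in both lists and KLF4 in DMSO alone. That lost share stood at percentile 0.020, and at 3.39 when matched on −log10 p. JUN, an AP-1 subunit gene, had 144 and 118 fragments.

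YAP and TEAD target genes had the highest lost share of the 18 lists with at least 5 DMSO-bound members. Of 22 members 10 had a peak in both lists and none in inflachromene alone, while 7 had one in DMSO alone, namely LATS2 and TEAD4 and, named after their values were seen, CCN2, AJUBA, F3, NUAK2 and FJX1. The lost share of 41.2% (18.4 to 67.1) stood at percentile 86.0 of lists matched on fold enrichment and 95.7 of lists matched on −log10 p, and so in neither case within the upper 2.5% of random lists. With each peak assigned to the nearest gene end within 50 kb, the lost share was 33.3% (6 of 18, percentile 57.8), equal to those of the mesenchymal and epithelial lists. With a window of 2500 bp it was 41.2% at percentile 92.0, below the 42.9% of the neuronal and liver list (3 of 7). LATS2, a kinase gene of the Hippo pathway, had 26 fragments in DMSO, and TEAD4, encoding a TEAD transcription factor, had 18. GADD45A, present in both lists, had 74 fragments in DMSO and 44 in inflachromene, and TEAD1 had 51 and 32.

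Of 25 mesenchymal and basal-like genes, 7 had a peak in both lists and 3 in DMSO alone (ZEB1, TGFB2 and MET), at percentile 13 and, matched on −log10 p, 45.0. CAV1, encoding caveolin, had 55 and 42 fragments. Of 25 epithelial and classical genes, 3 had a peak in both lists and 2 in DMSO alone (KRT19 and MUC1), at percentile 44.3; SOX9, encoding a ductal transcription factor, had 44 and 35 fragments. Of 25 senescence genes 8 had a peak in both lists and none in 1 list alone, at percentile 10.7. LMNB1, encoding lamin B1, had 49 and 43 fragments, and over the 8 genes the pileup was lower in inflachromene at 4 and higher at 4. Of 24 NF-kB and inflammatory genes 11 had a peak in both lists and NFKBIA in DMSO alone, at percentile 8.72 and, matched on −log10 p, 47.3; STAT3 had 102 and 72 fragments and RELB 65 and 38.

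Of 25 genes of the transcription and co-activator machinery, 20 had a peak in both lists and CDK12 in DMSO alone, at percentile 1.29 and, matched on −log10 p, 2.37. EP300, a histone acetyltransferase gene, had 63 and 28 fragments, with the DMSO summit 1004 bp from the gene's end. It does not stand for its list, whose 20 members in both lists had a median ratio of inflachromene to DMSO pileup of 0.819. Of 20 cholesterol and fatty acid synthesis genes, 17 had a peak in both lists and 2 in DMSO alone, IDI1 among them, at percentile 29.7. MVD, an enzyme gene of the mevalonate pathway, had 56 and 25 fragments. Of 22 glycolysis and hypoxia genes 13 had a peak in both lists and none in 1 list alone, at percentile 1.73, at 7.73 matched on −log10 p and, with the nearest gene end within 50 kb, at 39.3 (3 of 18 lost). Of 24 unfolded protein and stress genes 16 had a peak in both lists and TRIB3 in DMSO alone, at percentile 18.4. Of 28 constitutively expressed genes 21 had a peak in both lists, 3 in DMSO alone (PSMB2, PFN1 and UBB) and EEF2 in inflachromene alone, at percentile 5.82 and, matched on −log10 p, 24.3. The strongest PFN1 peak also lay at an end of ENO3, and the IDI1 peak at an end of WDR37. For the lists above with a single percentile, the one matched on −log10 p lay between 11.3 for senescence genes and 55.8 for epithelial and classical genes.

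Lists of markers of other cell types had few bound members. In the DMSO list 1 of 24 acinar and islet markers had a peak (PDX1), 3 of 24 immune markers (SPI1, CD68 and CSF1R), 2 of 22 fibroblast and endothelial markers (RGS5 and PDGFRB) and 4 of 24 neuronal and liver genes (APOA1, SNAP25, SYT1 and GRIN1). The CD68 peak also lay at an end of EIF4A1, the RGS5 peak at an end of NUF2, and CSF1R and PDGFRB shared a peak. CD14 had a peak of 10 fragments in inflachromene alone. The bound shares of these 4 lists and of the epithelial list lay in the lowest 2.5% of random lists, and those of 13 of the 22 lists in the highest 2.5%. Of the 18 lost shares, 4 lay in the lowest 2.5% and 0 in the highest; matched on −log10 p, 1 lay in the lowest.

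**Figure D3:**
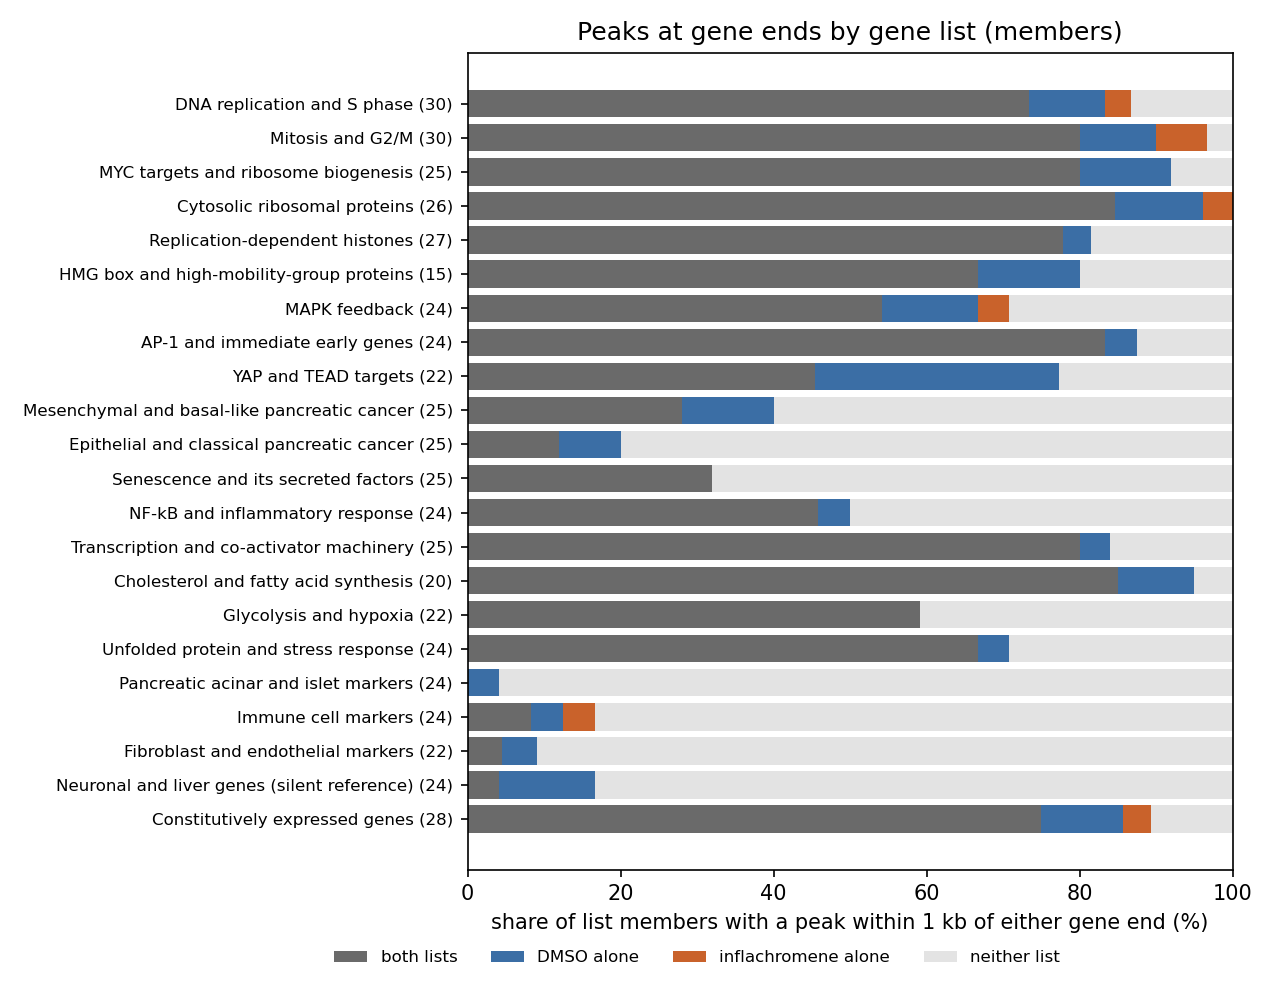
Share of the members of each gene list (%, horizontal axis; number of members in brackets) with a peak within 1000 bp of either gene end in both lists, in DMSO alone, in inflachromene alone or in neither. The YAP and TEAD list has the widest DMSO-alone segment, 7 of 22 members, and the lists of other cell types have few bound members.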

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

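Peaks on sequences outside the assembled chromosomes entered no comparison other than the alternative with all sequence names. Of 68 such sequences 15 had more peaks in inflachromene than in DMSO, 20 had fewer and 33 had equal numbers, 155 against 168 peaks in all. An unlocalised sequence assigned to chromosome 14 had 18 inflachromene peaks covering 5060 bp and 13 DMSO peaks covering 3090 bp. One assigned to chromosome 1 had 8 inflachromene peaks and 6 DMSO peaks. The mitochondrial chromosome had 4 inflachromene peaks covering 15149 bp against 1 DMSO peak covering 16281 bp, so the larger number went with a smaller covered length. Of the remaining 12 sequences with more inflachromene peaks, 9 had 1 peak against none, 1 had 2 against 1 and 2 had 3 against 2. No explanation was tested for these counts.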

How the results depend on the processing

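Matching lists on −log10 p, all sequence names for the overlap and the list without 19q13 were alternatives chosen after the data were examined. Each list's own summits were used for the first count of genes, and the main rule was set after that count was seen. By own summits 7254 genes had a peak in both lists, 1879 in DMSO alone and 338 in inflachromene alone. The main rule gave 7304, 1850 and 317. With 50% of each peak overlapping reciprocally, 58.8% of DMSO and 82.4% of inflachromene peaks were shared; with summits within 250 bp, 62.8% and 88.0%. With both lists at the shorter length the shares were 79.4% and 79.6%, as equal lengths bring them together by construction. At −log10 q of at least 5 the inflachromene share was 91.1%. Widening the gene-end window to 2500 bp gave 60.03% for all DMSO peaks, 66.2% for all inflachromene peaks, 68.9% for shared peaks, 44.0% for DMSO peaks alone and 41.2% for inflachromene peaks alone. Narrowing it to 500 bp gave 49.1%, 56.1%, 59.0%, 31.15% and 28.3%. At −log10 q of at least 5 the median widths were 311 bp for all DMSO peaks, 313 bp for all inflachromene peaks and 219 bp for DMSO peaks alone. The median fold enrichments were then 8.04 and 7.84 for all peaks, 9.45 for shared peaks, and 6.53 and 6.11 for DMSO and inflachromene peaks alone. The 4 gene lists with a lost share below the 2.5th percentile became 2 at 2500 bp and 1 when matched on −log10 p; the cause was not tested. With the nearest gene end within 50 kb they numbered 4 as well, but glycolysis and hypoxia rose to percentile 39.3 and MAPK feedback fell to 0.43. A threshold of −log10 q of at least 3 removed no peak and merging changed none, so neither says anything about stability. Without these settings, 39 of 66 alternative values of the comparisons stayed within the main value's interval or, for counts, within 1.5 times. The lost shares of single lists rest on few genes, with intervals too wide for such a count to show stability. The motif alternatives were not run. No called summit had fewer than 7 fragments, which limits what weak positions can show. No paired analysis was possible because each group holds 1 sample, and for the same reason no replicate could be left out.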

Other observations

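The tests of sequencing depth, of libraries per treatment, of the calling threshold and of the parts of 19q13 were set after their results were seen, the other 6 before, though after related summaries, and the runs, noncoding gene groups, single genes and loci that follow were chosen after their values were seen. The run with the most peaks away from protein-coding gene ends, with neighbouring peaks joined across gaps of at most 12.4 kb, was the 5S ribosomal RNA array on chromosome 1 (228608466 to 228646639), with 17 DMSO peaks of which 13 were kept in inflachromene. Clusters of transfer RNA genes on chromosome 16 (3150447 to 3191828) and chromosome 6 (27519377 to 27553636) had 8 and 6 DMSO peaks, of which 5 and 5 were kept. Other runs with transfer RNA genes, from 26550537 and 26305359 on chromosome 6 and 8220756 on chromosome 17, kept 3 of 5 each. One from 144545849 on chromosome 1 kept 6 of 6. Of 443 transfer RNA genes 112 had a DMSO peak within 100 bp of an end and 96 an inflachromene peak, and 30.4% (22.02 to 39.76) of these DMSO peaks had no inflachromene peak. The 5S array holds near-identical repeats, and some transfer RNA genes have copies of like sequence, so the gene a fragment came from can be uncertain. The loci of the long noncoding RNAs MALAT1 and NEAT1 on chromosome 11 kept 5 of 5 peaks each, and the run at VMP1 and MIR21 on chromosome 17 kept 4 of 6. Over all 19 runs of 5 or more such peaks 85 of 118 were kept, and 28.0% (20.1 to 37.0) had no inflachromene peak. Of all 6966 DMSO peaks away from gene ends, 49.3% (48.1 to 50.5) had none. These shares were not matched on peak strength. The lowest kept shares, 2 of 5 and 3 of 6, were in the runs nearest to TPSAB1 on chromosome 16 and AKR1E2 on chromosome 10.

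At 7267 of the 7304 genes with a peak in both lists, a DMSO peak overlapped an inflachromene peak, and the pair of highest mean pileup was compared, 6064 pairs in all since neighbouring genes share peaks. The median ratio of inflachromene to DMSO pileup was 0.822, and it was lower in inflachromene at 5621 genes. Of the 17 lists with at least 5 such genes, YAP and TEAD targets (ratio 0.677, lower at 10 of 10 genes, percentile 1.16 of 10000 random lists matched on mean pileup) and high-mobility-group genes (0.684, 8 of 10, percentile 1.92) had the lowest percentiles. Replication-dependent histones, whose 21 genes shared 16 pairs, had the highest (0.923, 15 of 21 lower, percentile 98.8), followed by senescence genes (0.996, 4 of 8, percentile 97.1) and replication genes (0.907, 15 of 22, percentile 96.2). With 17 lists compared, some percentiles near the ends arise by chance. Among the 1995 genes with a mean pileup of at least 40 fragments, the lowest ratio was at ZNF585A, with 57 fragments in DMSO and 24 in inflachromene (fold enrichments 17.5 and 9.65), where the Poisson intervals of 43.2 to 73.9 and 15.4 to 35.7 did not overlap. The highest was at AFF4, with 31 and 49 fragments (9.52 and 14.4), where those of 21.1 to 44.0 and 36.3 to 64.8 did. These intervals do not allow for the choice of each gene as an extreme of 1995 ratios.

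The inflachromene list was shorter by 4350 peaks. Lower depth over all sequences together falls short as the whole cause, because the pileup at strong shared summits was 0.804 times that in DMSO (0.794 to 0.817) while fragments numbered 0.964 times as many. That number includes mitochondrial and unplaced fragments, so a lower depth on the assembled chromosomes stays open. The highest mitochondrial −log10 q was 343.5 in DMSO and 704.9 in inflachromene. At the strong shared summits the median log2 ratio of inflachromene to DMSO local background was -0.135. The caller's larger minimum width for inflachromene also falls short as the whole cause. Among peaks at least 330 bp wide, DMSO peaks alone (672) still outnumbered inflachromene peaks alone (66) by 10.2 times (7.90 to 13.3). These 672 were a part of the 5390 DMSO peaks alone, whose median width was 213 bp. For the narrower ones, on which a minimum width would act, the test cannot decide. Scaling every DMSO summit by the ratio of strong shared peaks left 13561 DMSO peaks callable against 9796 that had an inflachromene peak, which passed the bound set beforehand; that bound was wrong because it took each noisy DMSO pileup, selected for passing the threshold, as the true level, so a uniform drop stays open. With 1 library per treatment, an effect of inflachromene and a lower enrichment of that one library cannot be told apart.

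DMSO peaks away from gene ends lacked an inflachromene peak 25.5 percentage points more often than those at gene ends. Weaker measured signal accounts for part of this, since matched on 10 equal groups by DMSO −log10 p the excess was 9.86 points (8.37 to 11.4), positive in 9 of 10 groups. Matched on width as well, it was 7.10 points (5.61 to 8.60). Both results passed the bound of 5 points set beforehand. The match took each noisy DMSO value, selected for passing the threshold, as the true level, and peaks away from gene ends were weaker as a class. What is left can thus still come from weaker true signal or narrower shape. In the 3 strongest groups, where 1.58% of peaks were lost, the matched log2 pileup ratio away from gene ends minus that at gene ends was -0.023 (-0.049 to 0.007). These groups hold few of the lost peaks, so that value does not show where the excess arose, and the calling threshold and a different response of weak sites away from genes both stay open.

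Strong peaks gathered between 38 and 41 Mb of chromosome 19, bounds chosen after the data were seen, which held 12 of the 50 strongest peaks by −log10 p in DMSO and 12 of 50 in inflachromene. The median local background up to 40.25 Mb was 10.05 fragments per base in DMSO and 10.46 in inflachromene, at least 4.47 times the 2.25 and 2.24 of the rest of the chromosome, but that bound was picked for it, and the 250 kb from 53.75 to 54 Mb, outside the segment, had medians of 13.35 and 11.56. From 40.25 to 41 Mb, the part left by that choice of bound, the median background was at most 1.22 times (0.925 to 1.44) that of the rest. This goes against a gain of copies by 1.5 times or more in that part alone, and the interval does not allow for the choice. The 10% quantile over the whole segment exceeded the median of the rest by 0.29 (-0.35 to 0.83). That quantile can come from the same lower part, so it does not speak for the segment up to 40.25 Mb. The median fold enrichment in the segment minus that of the rest was -1.37 in inflachromene and -1.56 in DMSO, but the background comes from the same library and rises with dense binding, so the bound set beforehand was wrong, and up to 40.25 Mb a gain of copies and dense binding cannot be told apart without an input library. Leaving the segment out changed neither overlap share beyond its interval.

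On chromosome 9 neither list had a peak between 21813315 and 22446614, which holds CDKN2A and CDKN2B, although 926 gaps at least that long occurred in the DMSO list.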
